A study of Mus musculus with 9 samples.

How the data were processed

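RNA from subcutaneous B16-F10 tumours taken on day 16 was extracted with TRIzol and sequenced as 9 libraries on a NovaSeq instrument, per the labels' protocols. The deposited files hold 1 column of whole-number counts per gene symbol for each library, which the authors made. The submitters' processing notes name STAR 2.7.0d and Cufflinks, and the human builds GRCh38 and hg38, although the files hold mouse gene symbols. The counter, the annotation and whether counting used strand are not given in the sources used here. Counts of a gene and of an overlapping gene on either strand can therefore not be told apart, and neither can close paralogs such as the globin, MHC and ribosomal protein genes. Of the 121 genes the naming rule selected, 33 have exons that overlap another gene in GENCODE M21, among them Fn1, Eng, Tap1, Top2a, Aldoa, Cd74, Cox4i1, Pmel and Rpl7a.

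The files list 54532 entries with 54427 distinct symbols. Of these symbols, 102 stand on several entries (207 entries), which were kept separate, 27 entries carry a date in place of a symbol, and 98.9% of symbols are in GENCODE M21. Groups came from the sample titles, since the genotype labels of the 6 Fbxo38 hairpin samples run from FBXO38 to FBXO43. Library totals of 15322163 to 17342554 counts set the counting precision, and no library was left out. Within groups, pairs of libraries differed by a chi-square per degree of freedom of 20.6 to 73.5 over genes, so none was treated as a second deposit of the same library. Some pairs from different groups differed by less, the lowest at 10.6, and this check does not show that libraries came from separate animals.

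Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total 15), TMM scaling, and a robust quasi-likelihood fit of all 9 libraries in 3 groups. The contrasts were each hairpin against control, their mean against control, and hairpin 2 against hairpin 1. The threshold was a Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM-scaled library sizes. The 41 gene lists of cell types and programmes were fixed before the data were examined. The 36 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the lists of a contrast. Camera with an estimated correlation, fry and an exact permutation of list levels stand beside it. None of the camera calls held with an estimated correlation. The NK cell, B and plasma cell, mast cell and basophil, keratinocyte, and adipocyte lists had 1, 4, 2, 4 and 2 tested members and were not tested. A list's mean log2 fold change is over edgeR values of its members, and its level is the mean log2 CPM per library.

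The genes named were set by a rule before the data were examined. They were Fbxo38 and Fbxo39 to Fbxo43, genes past the threshold by the size of their change, with the 3 of smallest p named as not past it where none passed, and up to 3 members of each list by mean CPM. Members that passed when adjusted over the list alone are named too, chosen after their values were seen. That adjustment does not cover the number of lists, so a few lists can hold a passing member by chance. Transcript length and GC content came from the longest transcript per symbol in GENCODE M21 (99.4% of tested genes). The simulations of shared controls drew unchanged groups 20 times; the one for genes shared at an unadjusted p under 0.05 was added after the values were seen.

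Alternatives were other scalings, filters, DESeq2 1.42.0, limma-voom with and without quality weights, fits of only the groups compared, a replicate block, a fold threshold and leaving out each library. Added after seeing the data were leaving out both libraries that stood apart, removing each library's length and GC trend, a fit without the robust option, and the exact permutation of list levels. The edgeR steps were tested on simulated counts for 14193 genes, 200 of them changed. For hairpin 2 against control, edgeR recovered 61% of genes changed 2-fold and 73% of those changed 4-fold with 4.3% false calls, and DESeq2 68% and 79% with 21.8% false calls. In simulated counts with no change, edgeR called 0 genes in each contrast. Camera called 0 lists in 3 contrasts and 1 in hairpin 2 against hairpin 1. That result does not calibrate camera for lists whose members vary together, as they do in the data. The estimated correlation was 0.82 for the matrix list and 0.95 for the interferon gamma list. Other splits of the real libraries gave up to 25 lists for the mean of both hairpins.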

Results

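The data were bulk RNA-seq gene counts from 9 libraries of tumours grown under the skin of C57BL/6 mice from B16-F10, a mouse melanoma cell line. The cells carried a control short hairpin RNA or 1 of 2 hairpins against Fbxo38, which encodes an F-box protein, the substrate-binding part of an SCF ubiquitin ligase. Tumours were taken on day 16, with 3 libraries in each of the 3 groups. The tissue holds host cells beside the melanoma cells. Counts per library summed to between 15322163 and 17342554, and 14193 genes were tested. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples. Along the first principal component (35.8% of the variance), replicate 1 labelled hairpin 1 lay at 60.6 and replicate 2 of hairpin 2 at -54.8, outside the range of the other libraries. Mitochondrial transcripts took 2.12% to 6.29% of the counts. Globin transcripts took 2.04% in replicate 2 of hairpin 2 and at most 0.481% in each other library.

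The first question was whether the hairpins lowered the targeted transcript. Fbxo38 (ENSMUSG00000042211.7, a protein-coding gene on the minus strand of GRCm38 chromosome 18, 62504155 to 62548695, with no overlapping gene in GENCODE M21) stood at 27.9 ± 5.41 CPM in the control libraries (SD, n = 3). It stood at 14.7 ± 5.38 CPM with hairpin 2 (SD, n = 3), 52.8% of control in the fitted ratio. The log2 fold change was -0.92 (SE 0.29, 95% interval -1.56 to -0.28), with an edgeR unadjusted p of 0.00964 and an adjusted p of 0.254 over all tested genes. All 3 hairpin 2 libraries, at 20.9, 11.4 and 11.9 CPM, lay below all 3 controls, at 21.6, 31.3 and 30.7 CPM. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. In the libraries labelled hairpin 1, Fbxo38 stood at 35.1, 20.96 and 22.0 CPM (26.0 ± 7.86, SD, n = 3). Their log2 fold change against control was -0.10 (SE 0.28, 95% interval -0.73 to 0.53; edgeR adjusted p = 1; exact two-sided permutation p = 0.9), so a lower Fbxo38 level was not detectable there. These libraries are therefore called by their label throughout. The difference between the hairpins was -0.82 (SE 0.29; edgeR unadjusted p = 0.0171, adjusted p = 0.376). The genotype labels of the 6 Fbxo38 hairpin samples name FBXO38 to FBXO43 in turn. Fbxo42 differed by 0.01 (SE 0.15) with hairpin 2 and by -0.12 (SE 0.15) in the libraries labelled hairpin 1. Fbxo39, Fbxo40 and Fbxo43 averaged under 0.4 CPM in every group. Fbxo41 averaged at most 1.32 CPM.

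**Figure D1:**
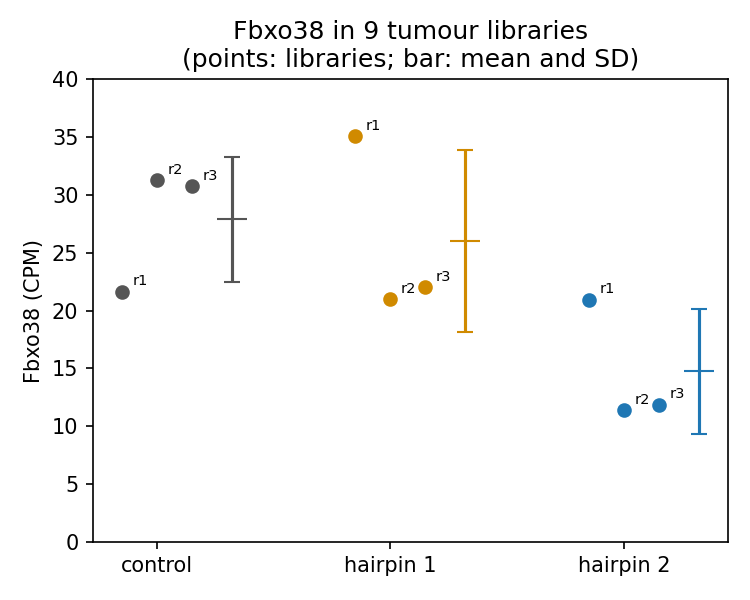
Fbxo38 in CPM, counts scaled to library size (vertical axis), in each of the 9 libraries, by group; points are libraries with their replicate number, and the bars beside them are the group mean and SD (n = 3). The hairpin 2 libraries sit between 11.4 and 20.9 CPM, below the 3 controls, while those labelled hairpin 1 span 20.96 to 35.1 CPM.

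The libraries labelled hairpin 1 were compared with control, with the limit that their Fbxo38 level did not differ detectably. Genes of fibroblasts and fibrillar matrix were higher as a list. All 16 measured members had a positive log2 fold change, with a mean of 1.93 (camera adjusted p = 3.2e-10; adjusted p = 0.95 with an estimated correlation). Col1a1, a chain of type I collagen, stood at 685 ± 804 CPM against 125 ± 71.9 in control (SD, n = 3). Fibronectin (Fn1) stood at 334 ± 244 against 160 ± 53.5 CPM, and the matrix glycoprotein gene Sparc at 784 ± 381 against 532 ± 101 CPM. Endothelial genes were also higher, by a mean of 0.37 over 14 members (camera adjusted p = 0.00116; 0.95 as adjusted p with an estimated correlation). Eng, encoding endoglin and the most abundant of the named endothelial genes, went the other way, at 403 ± 30.8 against 453 ± 21.9 CPM. Cdh5, the endothelial cadherin, stood at 58.4 ± 18.0 against 44.5 ± 5.74 CPM, and Plvap at 66.0 ± 6.71 against 51.3 ± 10.95 CPM. Pericyte and smooth muscle genes (mean 0.39, adjusted p = 0.0247), glycolysis and hypoxia genes (0.26, adjusted p = 0.000754), lysosome genes (0.12, adjusted p = 0.0378) and ribosomal protein genes (0.08, adjusted p = 0.0378) were higher by camera, each with an adjusted p of 0.95 with an estimated correlation. Without replicate 1 labelled hairpin 1, the matrix mean was 0.82 and kept its call. The endothelial (mean 0.26), pericyte (0.25), glycolysis (0.13), lysosome (0.06) and ribosomal (-0.01) calls were lost. The glycolysis call was also lost without replicate 2 labelled hairpin 1 (0.20). The pericyte call was lost without control replicates 1 (0.40) and 3 (0.37) and replicate 3 labelled hairpin 1 (0.48). The lysosome call was lost without control replicates 1 (0.10) and 3 (0.07), replicate 2 labelled hairpin 1 (0.09) and replicate 1 of hairpin 2 (0.12). The ribosomal call was also lost without control replicates 2 (0.05) and 3 (0.075), replicate 3 labelled hairpin 1 (0.09), and replicates 1, 2 and 3 of hairpin 2 (0.07, 0.07 and 0.075), and its mean was 0.12 without replicate 2 labelled hairpin 1. Without control replicate 2 the pericyte mean was 0.75 and the lysosome mean 0.21, and without replicate 2 labelled hairpin 1 the pericyte mean was 0.65. With the length and GC trend removed the ribosomal call was lost as well (0.048). Rpl7a, a ribosomal protein gene outside the list whose exons overlap small RNA genes, went the other way, at 176 ± 9.64 against 257 ± 25.3 CPM.

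Cell cycle genes were lower as lists in the libraries labelled hairpin 1. All 18 G2 and M phase genes had a negative log2 fold change, with a mean of -0.23 (camera adjusted p = 3.2e-10), as did 16 of the 17 S phase genes, with a mean of -0.22 (camera adjusted p = 2.41e-09). The adjusted p was 0.714 for both lists with an estimated correlation. Mcm2, a subunit of the replicative helicase, stood at 522 ± 58.4 against 623 ± 22.3 CPM. Rrm1 and Mcm6 had log2 fold changes of -0.29 (SE 0.11) and -0.28 (SE 0.11), and Ccnb1, encoding cyclin B1, one of -0.32 (SE 0.10). Erythroid genes were lower over 8 members (mean -1.47; camera adjusted p = 0.0167). Their adjusted p was 0.95 with an estimated correlation. Hba-a1 and Hbb-bs, the globin genes, stood at 552 ± 121 and 511 ± 94.3 CPM against 1588 ± 608 and 1423 ± 658. Cholesterol and fatty acid synthesis genes had a mean of -0.13 (camera adjusted p = 0.0247; adjusted p = 0.95 with an estimated correlation). The S phase and G2 and M phase calls held without any single library. The erythroid call was lost without control replicate 2 (mean -1.24) or any replicate labelled hairpin 1 (-1.57, -1.44 and -1.48 without 1, 2 and 3). The cholesterol call was lost without control replicate 3 (-0.03) or replicate 1 labelled hairpin 1 (-0.001), and its mean was -0.22, -0.21 and -0.22 without control replicate 2 and replicates 2 and 3 labelled hairpin 1.

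No single gene passed edgeR's threshold in the libraries labelled hairpin 1 (0 of 14193 at an adjusted p under 0.05; lowest adjusted p = 1). At an unadjusted p under 0.05 there were 450 genes, against 710 by chance, 206 without control replicate 3, and DESeq2 and limma-voom called 0. The genes of smallest p, none past the threshold, were Rpl7a, Snai1 and Id3. Snai1, a transcription factor of the epithelial-to-mesenchymal transition, had a log2 fold change of 2.12 (SE 0.44), at 3.33 ± 1.32 against 0.761 ± 0.248 CPM. Id3, an inhibitor of helix-loop-helix factors, stood at 10.6 ± 3.45 against 3.92 ± 0.342 CPM. Adjusted over the list alone, 2 list members passed, Snai1 and Cdc6, a replication licensing gene (log2 fold change -0.48, SE 0.12). With no adjustment for the number of lists, passes in a few lists can come by chance, so these 2 do not show a change.

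With hairpin 2, the matrix list was again higher than in the same control libraries. All 16 members were positive, with a mean of 1.64 (camera adjusted p = 0.000223; adjusted p = 0.887 with an estimated correlation). Col1a1 stood at 289 ± 257 CPM, Fn1 at 344 ± 184 and Sparc at 682 ± 181 (SD, n = 3). S phase genes were lower, 16 of 17 members negative with a mean of -0.21 (camera adjusted p = 0.000223; adjusted p = 0.887 with an estimated correlation). Mcm2, Rrm1 and Mcm6 had log2 fold changes of -0.10 (SE 0.11), -0.15 (SE 0.11) and -0.20 (SE 0.11). Both calls held without any single library, the matrix mean being 0.78 without replicate 3 of hairpin 2.

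Interferon and antigen presentation genes were lower as lists with hairpin 2. All 21 type I interferon response genes were negative, with a mean of -0.64 (camera adjusted p = 0.000223). All 16 MHC class I presentation genes were negative, with a mean of -0.41 (adjusted p = 0.016), as were 15 of 16 interferon gamma response genes, with a mean of -0.48 (adjusted p = 0.016). Each had an adjusted p of 0.887 with an estimated correlation. Bst2, encoding tetherin, stood at 141 ± 105 against 232 ± 75.04 CPM. B2m, the light chain of MHC class I, stood at 750 ± 509 against 1052 ± 216 CPM, and H2-D1, a heavy chain, at 687 ± 512 against 1039 ± 188 CPM. Tap1, the peptide transporter gene, whose exons overlap Psmb9, stood at 112 ± 103 against 189 ± 58.3 CPM, and Irgm1 at 152 ± 116 against 251 ± 71.1 CPM. Without replicate 2 of hairpin 2, none of the 3 calls held, and the means were -0.31, -0.003 and -0.01 for the type I interferon, MHC class I and interferon gamma lists. Without control replicate 1 or 2, the MHC class I and interferon gamma calls were also lost, with MHC class I means of -0.41 and -0.21 and interferon gamma means of -0.54 and -0.23; the type I interferon mean was -0.35 without control replicate 2. Without replicate 3 of hairpin 2 the 3 means were -1.49, -1.22 and -1.26. Nuclear oxidative phosphorylation genes had a mean of -0.13 over 19 members (camera adjusted p = 0.03; adjusted p = 0.887 with an estimated correlation). Atp5b and Cox4i1 of that list had log2 fold changes of -0.04 (SE 0.12) and -0.06 (SE 0.10). That call was lost without control replicate 3 (mean -0.10) or replicate 2 of hairpin 2 (mean -0.07), and its mean was -0.20 without replicate 3 of hairpin 2. With each library's trend in transcript length and GC content removed, the oxidative phosphorylation mean was 0.002 (camera adjusted p = 0.813), so neither its direction nor its call was kept.

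No gene passed edgeR's threshold with hairpin 2 (0 of 14193; lowest adjusted p = 0.242), while 2046 genes had an unadjusted p under 0.05, against 710 by chance. DESeq2 called 303 genes, 157 higher and 146 lower, and limma-voom called 0. The genes of smallest p, none past edgeR's threshold, were Crebrf, Timm50 and Chaf1b. Crebrf, a regulator of the CREB3 stress pathway, stood at 42.6 ± 7.14 against 20.99 ± 0.488 CPM (log2 fold change 1.02, SE 0.17). Timm50, of the mitochondrial import machinery, stood at 86.6 ± 6.05 against 127 ± 3.86 CPM (-0.55, SE 0.09). Chaf1b, of the histone chaperone CAF-1, stood at 71.0 ± 7.90 against 113 ± 0.595 CPM (-0.67, SE 0.12). Adjusted over the list alone, with no adjustment for the number of lists, 7 list members passed. Cdk1, Plk1 and Ccne1, of the cell cycle lists, had log2 fold changes of -0.35 (SE 0.08), -0.40 (SE 0.11) and -0.45 (SE 0.11). The others were Tgfbr1 at 0.56 (SE 0.11), Snai1 at 1.82 (SE 0.44), the melanosome transport gene Rab27a at 0.46 (SE 0.11) and Cdh19 at 0.56 (SE 0.18). The count at an unadjusted p under 0.05 was 1113 without replicate 2 of hairpin 2, 1330 without control replicate 2 and 1137 without control replicate 3.

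Fold changes with hairpin 2 went with transcript length. Across 14106 genes, which are not independent replicates, Spearman's rho between log2 fold change and transcript length was 0.373, and between log2 fold change and GC content -0.25. The values in the libraries labelled hairpin 1 were -0.019 and 0.03. Genes higher at an unadjusted p under 0.05 with hairpin 2 had a median transcript length of 5960 bases, those lower had one of 2239, and all tested genes one of 3206. Per library, the rank correlation between a gene's deviation from its mean and its length was 0.329, 0.325 and 0.112 in the 3 hairpin 2 libraries, -0.309, -0.088 and 0.017 in those labelled hairpin 1, and -0.013, -0.233 and -0.198 in the controls.

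**Figure D2:**
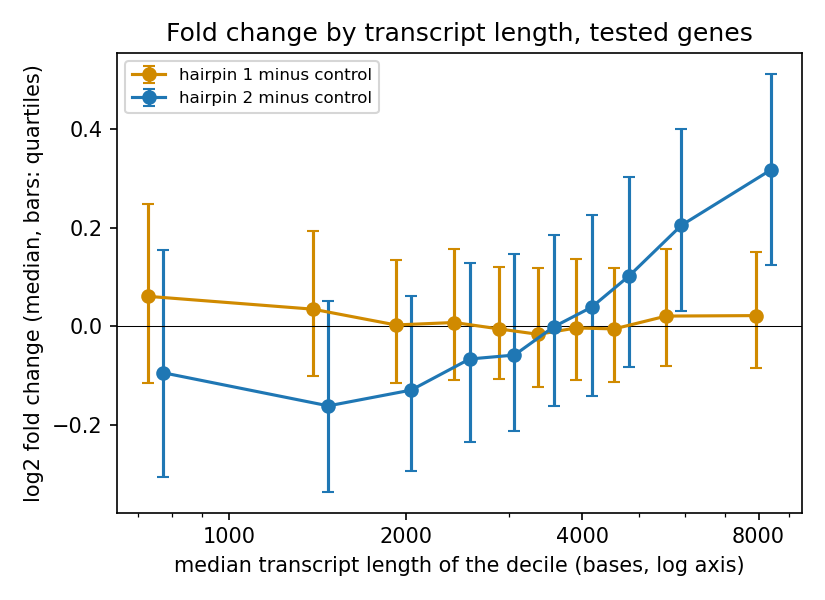
Log2 fold change against control (vertical axis) by the median transcript length in bases of each length decile (horizontal log axis) for the libraries labelled hairpin 1 and hairpin 2, drawn slightly apart; points are medians over about 1410 genes and bars the quartiles. The hairpin 2 medians lie at -0.09 in the shortest decile and 0.32 in the longest, and those labelled hairpin 1 at 0.06 and 0.02.

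The mean of both hairpins was set against control to ask which changes the hairpins had in common, with the limit that a lower Fbxo38 was not detectable in the libraries labelled hairpin 1. The matrix list was higher by a mean of 1.78, all 16 members positive (camera adjusted p = 4.07e-08), as were the endothelial list by 0.35 (adjusted p = 0.0105) and the pericyte list by 0.46 (adjusted p = 0.031). Lists of S phase (-0.22, adjusted p = 8.35e-08), G2 and M phase (-0.12, adjusted p = 0.000237), type I interferon (-0.355, adjusted p = 0.00199) and cholesterol and fatty acid synthesis genes (-0.15, adjusted p = 0.0105) were lower. All 7 had an adjusted p of 0.983 with an estimated correlation. Of these, the matrix and S phase lists passed camera in each hairpin on its own. Both comparisons use the same control libraries, so the calls are not independent. The G2 and M phase list passed labelled hairpin 1 (-0.23) but stood at -0.02 with hairpin 2 (adjusted p = 0.277), and the type I interferon list passed with hairpin 2 (-0.64) but stood at -0.08 labelled hairpin 1 (adjusted p = 0.363). The hairpins differed from each other in both lists by camera, with an adjusted p of 0.955 for each with an estimated correlation; the type I interferon difference was -0.12 without replicate 1 labelled hairpin 1 and -0.22 without replicate 2 of hairpin 2, and the G2 and M phase difference 0.15 and 0.13 without replicate 1 labelled hairpin 1 and replicate 1 of hairpin 2, each then missing the threshold. The endothelial, pericyte and cholesterol lists passed labelled hairpin 1 and missed the threshold with hairpin 2, with means of the same direction (0.32, 0.54 and -0.17). Among matrix genes, the type III collagen gene Col3a1 averaged 325 CPM labelled hairpin 1 and 194 with hairpin 2 against 57.4 in control, and Lox, which crosslinks collagen, 31.9 and 12.1 against 1.3 CPM; these 2 were chosen after their values were seen. The S phase list lay below every control in all 6 libraries labelled hairpin 1 or 2, at 6.68 to 6.92 against 6.96 to 7.06 mean log2 CPM (exact two-sided permutation p = 0.0238; adjusted p = 0.857 over 36 lists). The matrix list lay above every control in 4 of 6. Without control replicate 2 the type I interferon mean was -0.07 and without replicate 2 of hairpin 2 it was -0.20, and the call was lost in both; it ran to -0.78 without replicate 3 of hairpin 2, and was -0.54, -0.60 and -0.20 without control replicate 3 and replicates 1 and 3 labelled hairpin 1. The endothelial call was lost without control replicate 1 (mean 0.36) or replicate 1 labelled hairpin 1 (0.29). The pericyte call was lost without control replicates 1 (0.47) and 3 (0.43), replicate 1 labelled hairpin 1 (0.39) and replicate 2 of hairpin 2 (0.27), and its mean was 0.81 without control replicate 2. The cholesterol call was lost without control replicate 3 (-0.05), replicate 1 labelled hairpin 1 (-0.09) and replicate 3 of hairpin 2 (-0.11), and its mean was -0.24 without control replicate 2.

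No gene passed edgeR's threshold in this comparison (0 of 14193; lowest adjusted p = 0.674), with 1034 at an unadjusted p under 0.05 (418 without control replicate 3), 8 called by DESeq2 and 0 by limma-voom. Adjusted over the list alone, with no adjustment for the number of lists, 10 list members passed. They were the S phase genes Cdc6, Mcm5, Rrm2, Mcm7, Ccne1 and Mcm3, with log2 fold changes from -0.40 to -0.27, the mitotic kinases Cdk1 (-0.26, SE 0.07), Aurka (-0.28, SE 0.08) and Plk1 (-0.36, SE 0.09), and Snai1 (1.97, SE 0.40). No gene passed the threshold in both hairpins. The 3 with the smallest p in both were Snai1, Cxcr4 and Ephb3. Cxcr4, a chemokine receptor gene, stood at 9.94 ± 1.64 CPM labelled hairpin 1 and 11.4 ± 3.82 with hairpin 2, against 4.31 ± 1.53 in control. Ephb3, an ephrin receptor gene, stood at 1.39 ± 0.517 and 1.64 ± 1.55 CPM against 0.0396 ± 0.0686, too few control reads for a fold change. For agreement across genes, each hairpin's difference from control was taken between group means of log2 CPM, not from edgeR. These differences correlated at 0.533, against 0.503 (0.481 to 0.528) in 20 simulations of unchanged groups sharing the controls. Their covariance was 0.0822 against 0.0763 (0.0722 to 0.0828). The sign of these differences was the same for 62.7% of genes, against 66.9% simulated. At an unadjusted p under 0.05, 119 genes were higher and 76 lower in both, against 78.0 (66 to 91) and 57.8 (45 to 67) in 20 simulations of unchanged groups sharing the controls and 21.3 and 11.8 for independent lists. The simulated lists averaged 634 and 629 genes against 450 and 2046 here, so the overlaps cannot be compared directly. Unchanged groups also overlapped through the shared controls, so the excess over independent lists does not show a common effect of the hairpins. Agreement beyond the shared controls was not clear. The same sign was less frequent than in any simulation (65.8% to 67.6%), while the correlation lay just above its simulated range. The simulations drew each gene independently, while genes vary together in the data. Their ranges are therefore too narrow to decide either point.

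**Figure D3:**
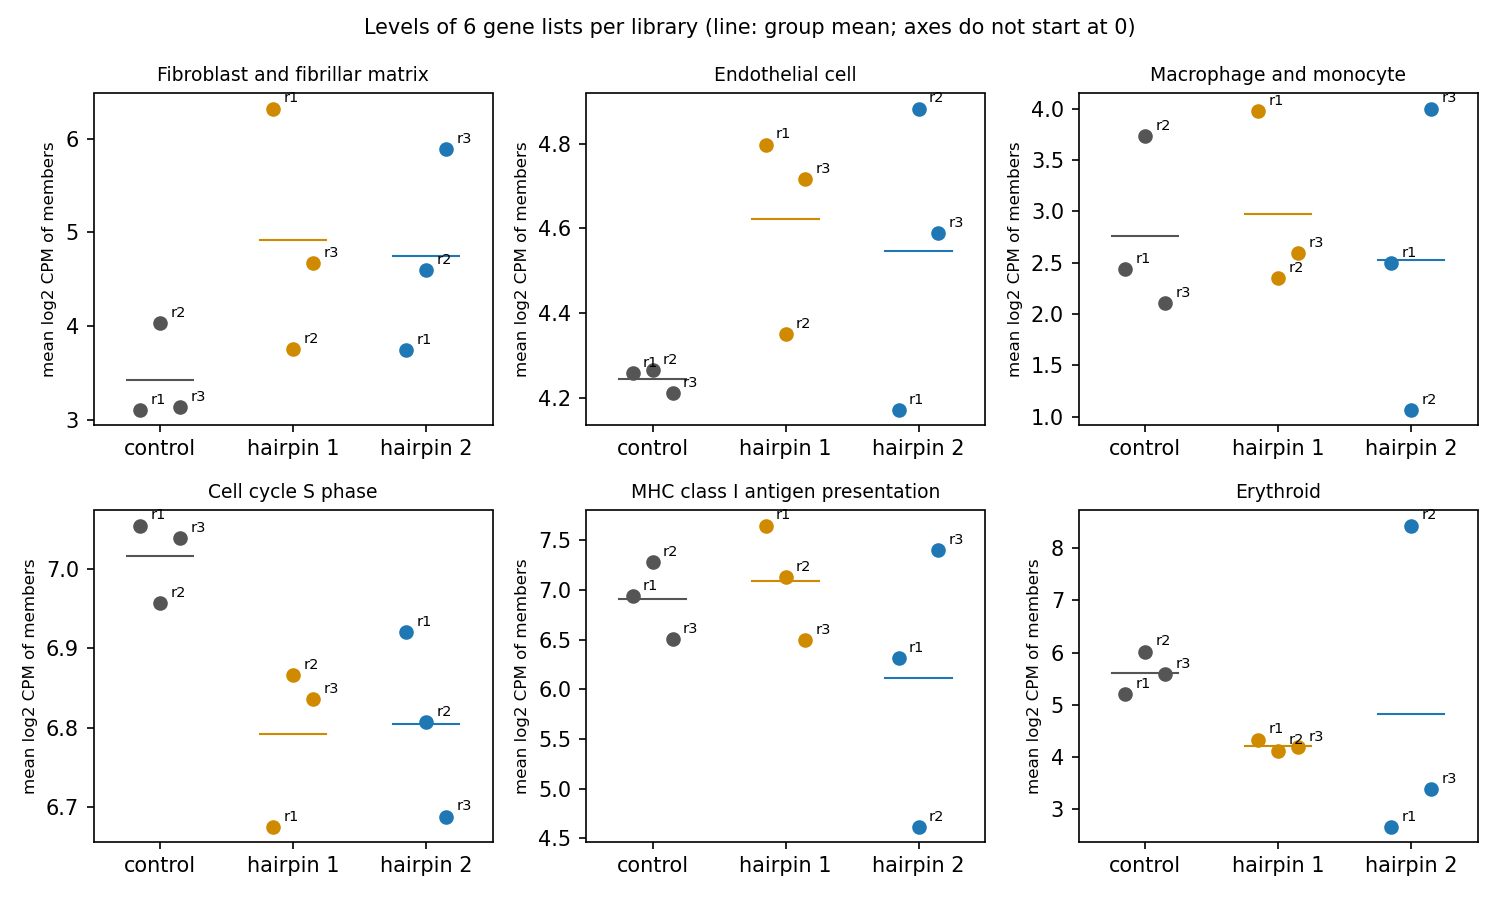
Level of 6 gene lists (vertical axes, mean log2 CPM of the tested members) in each of the 9 libraries by group; points are libraries with their replicate number and lines the group means. The S phase list lies lower in all 6 libraries labelled hairpin 1 or 2 than in the 3 controls, the matrix list reaches 6.32 in replicate 1 labelled hairpin 1, and the MHC class I list falls to 4.62 in replicate 2 of hairpin 2.

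The hairpins were compared with each other to ask whether their effects differed. Lists of cytotoxic lymphocyte, type I interferon, interferon gamma, MHC class I, MHC class II, glycolysis, nuclear oxidative phosphorylation and ribosomal protein genes were lower with hairpin 2 than in the libraries labelled hairpin 1, and the G2 and M phase list was higher by 0.21. These 9 passed by camera, each with an adjusted p of 0.955 with an estimated correlation. Top2a and Mki67, markers of dividing cells, stood at 576 ± 78.5 and 305 ± 105 CPM with hairpin 2, against 430 ± 51.7 and 204 ± 57.0 labelled hairpin 1. The glycolytic genes Eno1 and Aldoa stood at 7684 ± 513 and 4398 ± 652 against 9242 ± 938 and 5677 ± 940 CPM. Cd74, the MHC class II invariant chain, stood at 193 ± 216 against 355 ± 151 CPM, H2-Aa at 69.2 ± 80.1 against 133 ± 56.5 CPM, and the granzyme gene Gzmb at 2.08 ± 2.27 against 5.60 ± 4.43 CPM. With both libraries that stood apart left out, the means of the MHC class I, MHC class II, interferon gamma, type I interferon and cytotoxic lists turned positive, and the interferon gamma list then passed as higher with hairpin 2 (0.54, camera adjusted p = 0.0019). Of these 5, in that order, the means were -0.31, -0.36, 0.06, -0.12 and -0.11 without replicate 1 labelled hairpin 1 and -0.21, -0.16, -0.19, -0.22 and -0.35 without replicate 2 of hairpin 2, and only MHC class I in the former kept its call. Without replicate 3 of hairpin 2 they were -1.43, -2.01, -1.45, -1.41 and -2.45, and without replicate 3 labelled hairpin 1 the interferon gamma and type I interferon means were -1.04 and -0.86. The cytotoxic call was also lost without control replicates 1 (-0.805) and 3 (-0.81), replicate 2 labelled hairpin 1 (-0.83) and replicate 1 of hairpin 2 (-0.53). The G2 and M phase and ribosomal calls were lost without replicate 1 labelled hairpin 1 (0.15 and -0.04) or replicate 1 of hairpin 2 (0.13 and -0.06), and the ribosomal mean was -0.17 without replicate 2 labelled hairpin 1. The glycolysis call was lost without replicate 1 labelled hairpin 1 (-0.10) or replicate 3 of hairpin 2 (-0.20), and its mean was -0.34 without replicate 3 labelled hairpin 1. The oxidative phosphorylation call held without any single library, at -0.12 without replicate 2 of hairpin 2. With the length and GC trend removed, the ribosomal mean turned to 0.07 (camera adjusted p = 0.176) and the oxidative phosphorylation mean was -0.04 (adjusted p = 0.328), so both calls were lost. No gene passed edgeR's threshold (0 of 14193; lowest adjusted p = 0.375), 1654 had an unadjusted p under 0.05 (974 without replicate 1 labelled hairpin 1, 738 without replicate 2 of hairpin 2), DESeq2 called 89 and limma-voom 0. The genes of smallest p, none past the threshold, were Vps13c at 92.6 ± 0.196 against 59.5 ± 7.25 CPM, the myosin gene Myo5a, which moves melanosomes, at 678 ± 91.5 against 410 ± 71.2 CPM, and Timm50. Adjusted over the list alone, Tgfbr1 (0.52, SE 0.11), Slc16a3, a lactate transporter gene (-0.51, SE 0.11), and Trp53inp1 (0.78, SE 0.18) passed. These passes carry no adjustment for the number of lists, so they can come by chance.

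Melanocyte genes, the identity of the tumour line, did not pass as a list in any comparison. The list stood at 8.75 ± 0.078 mean log2 CPM in control, 8.84 ± 0.088 labelled hairpin 1 and 8.86 ± 0.172 with hairpin 2 (SD, n = 3). Tyrp1, Dct and Pmel, which make pigment and melanosomes, averaged 8116, 7189 and 5739 CPM in control and had log2 fold changes between -0.17 and 0.06 in both groups. Host immune lists varied more between libraries than between groups. The macrophage list ran from 2.10 to 3.73 in control, 2.35 to 3.97 labelled hairpin 1 and 1.07 to 4.001 with hairpin 2, and the T cell list from -0.44 to 0.81, -0.50 to 1.14 and -1.35 to 1.09. Lyz2 and C1qa, of macrophages, had log2 fold changes of 0.41 (SE 0.94) and 0.15 (SE 0.99) labelled hairpin 1, and 0.30 (SE 0.94) and -0.01 (SE 1.00) with hairpin 2. The erythroid list in hairpin 2 had a mean log2 fold change of 1.27, all 8 members positive, from replicate 2, while the mean of its log2 levels was lower by 0.78 (difference -0.78). Its level was 8.43 in that library, 2.66 and 3.39 in the other hairpin 2 libraries, and 5.20 to 6.02 in control.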

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

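The tests with the length and GC trend removed in hairpin 2 against hairpin 1 and in gene lists, with both libraries that stood apart left out, on the matrix list and on replicate 2 of hairpin 2 were chosen after the results were seen. The predictions of the other tests were written down before their results were seen. Removing the trend in hairpin 2 against control was among these, although as a setting it was added after the data were seen.

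For 9 gene lists the effects of the hairpins differed in camera's test of hairpin 2 minus the libraries labelled hairpin 1. The mean differences were -0.946 for cytotoxic lymphocyte genes (camera adjusted p = 0.0482), -0.559 for type I interferon (0.00451 adjusted), -0.672 for interferon gamma (0.0103), -0.633 for MHC class I (0.00145), -0.686 for MHC class II (0.014), 0.207 for G2 and M phase (0.00911), -0.221 for glycolysis and hypoxia (0.00637), -0.187 for nuclear oxidative phosphorylation (0.00133) and -0.108 for ribosomal proteins (0.018). With an estimated correlation each adjusted p was 0.955. With 1 library left out, 8 of the 9 lost their call at least once, oxidative phosphorylation excepted; the cytotoxic mean ran from -2.448 to -0.113 and the interferon gamma mean from -1.447 to 0.057. With both libraries that stood apart left out, the 5 immune means turned positive, interferon gamma to 0.539. With the length and GC trend removed, the ribosomal mean turned to 0.07 and the oxidative phosphorylation call was lost at -0.037. Of the 10 splits of these 6 libraries, 8 gave as many lists, the real split 9 and the highest other 22. The splits are too few for a share under 0.05.

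The lower MHC class I and interferon gamma levels with hairpin 2 (-0.80 and -0.97 against control) came mostly from 1 library, replicate 2. The lower type I interferon level may come from it in part. Without replicate 2 the MHC class I level differed from control by -0.052, the interferon gamma level by -0.03 and the type I interferon level by -0.39, each within the SD among controls (0.39, 0.415 and 0.456). With that library the type I interferon difference was -0.92, and whether the rest is more than spread between libraries stays open. Replicate 1 of hairpin 2 lay at 6.31, 5.21 and 3.20 for MHC class I, interferon gamma and type I interferon, below every control. Replicate 3 lay at 7.40, 6.10 and 4.55, above the control means of 6.91, 5.68 and 4.26. Replicate 2 of hairpin 2 had 2.04% globin counts and the lowest macrophage, T cell and cytotoxic lymphocyte levels, 1.07, -1.35 and -1.56. A biological effect of hairpin 2 on this pathway stays untested.

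The matrix list was higher by 1.41 in level in the 6 libraries labelled hairpin 1 or 2, of which those labelled hairpin 1 showed no detectable drop of Fbxo38 (exact two-sided permutation p = 0.0952 for the list). The matrix list minus the macrophage list was higher in all 6 than in every control, by 1.42 (unadjusted exact two-sided permutation p = 0.0357, 84 splits). The macrophage list itself differed by -0.01. The difference was largest, at 3.53, in replicate 2 of hairpin 2, where the macrophage level was lowest. Both lists were chosen after their values were seen, so this cannot decide against a share of host tissue raised alike for every cell type. The endothelial and pericyte lists moved with the matrix, by 0.34 and 0.43, so more stromal and vascular tissue stays open. Replicate 1 labelled hairpin 1 alone is argued against, since without it the level difference was 1.109 (SE 0.50). A fibroblast response and matrix expression by the melanoma cells stay open as biological explanations, both untested.

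The excess of genes at an unadjusted p under 0.05 with hairpin 2 goes with transcript length. Once each library's trend with length and GC was removed, the count went from 2046 to 1362, 918 of them among the 2046. It stayed above 1.5 times the 705 given by chance, so the trend removed did not account for the whole count against control. Genes vary together, so counts can spread widely around the 705. Another split of these libraries reached 1599 before the removal, and no split was rerun after it. An excess over chance after the removal is therefore not shown. Against the libraries labelled hairpin 1 the count went from 1654 to 843, 526 of them among the 1654. That is within 1.5 times chance, so there the trend could account for most of the excess. A biological effect of hairpin 2 on long transcripts stays untested.

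Other splits of the same libraries bear on chance. For hairpin 2 against control, 1 of 10 splits, the real one, gave 2046 genes (highest other 1599) and 1 gave 303 DESeq2 genes (highest other 16), while all 10 gave at least the 6 gene lists of the real split (highest other 21). Between hairpins, 2 of 10 gave as many genes (real 1654, highest other 2255). For the libraries labelled hairpin 1 against control, 4 of 10 gave as many genes (real 450, highest other 2495) and 6 of 10 as many lists (real 10, highest other 21). All of these splits are too few for a share under 0.05. Why some splits of the libraries labelled hairpin 1 and the controls gave several times the real count was not tested. For the mean of both hairpins, 17 of 100 drawn splits (of 840) gave as many genes (real 1034, highest other 3402) and 78 of 100 as many lists (real 7, highest other 25), so chance is not excluded.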

How the results depend on the processing

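The tests with both libraries that stood apart left out, the length and GC trend removed, no robust option and exact permutation of list levels were chosen after seeing the data. Causes were not tested. The direction of Fbxo38 with hairpin 2 held in every setting (-0.77 to -1.26 with 1 library left out). In the libraries labelled hairpin 1 its change ran from -0.391 to 0.026 with 1 library left out, turning positive without their replicate 2 (0.026) or 3 (0.005). Under the replicate block the values were -0.167 and -0.996, and pairing by replicate number changed no count of genes (0). The camera calls of the ribosomal and lysosome lists labelled hairpin 1 and of the cytotoxic list between hairpins did not pass under it, and no other call changed. The replicate numbers are not said to pair the samples, and no pairing by number was seen. Of 9 same-number pairs, 2 correlated above 0.1 (-0.41 to 0.14), and 0 libraries correlated best with their own number. With 3 libraries per group, this check cannot exclude a pairing.

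Gene counts of 0 by edgeR held under other scalings, a stricter filter, limma-voom, a fold threshold and the added settings. DESeq2 called 303 genes for hairpin 2, 8 for the mean and 89 between hairpins. With no filter on low counts, 4 passed for hairpin 2 (Crebrf, Myo5a, Eva1b and Ubn2) and 2 between hairpins (Gm23935 and Gm24270). Leaving out 1 library gave 0 to 2 for hairpin 2 and 0 to 1 between hairpins, all without its replicate 1 (Cdk2ap1 and Mgp, then Cdk2ap1). These genes were named after their values were seen. Gene list counts fell to 0 in all 4 comparisons with an estimated correlation, fry or exact permutation, and rose from 6 to 11 for hairpin 2 with no filter. Leaving out 1 library gave 4 to 14 lists labelled hairpin 1, 4 to 13 for hairpin 2, 5 to 12 for the mean and 4 to 14 between hairpins.

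Signs turned for these list means. Ribosomal proteins labelled hairpin 1 ran from -0.009 (without their replicate 1) to 0.121, and stood at -0.008 with both libraries that stood apart left out. Between hairpins, interferon gamma ran from -1.447 to 0.057 (without replicate 1 labelled hairpin 1). With both left out, the means between hairpins were 0.342 for cytotoxic lymphocyte, 0.228 for type I interferon, 0.539 for interferon gamma, 0.119 for MHC class I and 0.171 for MHC class II genes. With the length and GC trend removed, oxidative phosphorylation stood at 0.002 for hairpin 2 and ribosomal proteins at 0.07 between hairpins. The median log2 fold change of all genes moved by at most 0.045 from its value in the tests reported.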

Other observations

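The tests on lymphocyte and macrophage genes were chosen after the result was seen. DESeq2 called 8 genes for the mean of both hairpins, none of which passed edgeR's threshold (adjusted p = 0.674 for each). Higher were Eln, which encodes elastin (log2 fold change 3.09, SE 0.67; DESeq2 adjusted p = 0.0238), Rcn3 (1.42, SE 0.32), Cxcr4 (1.30, SE 0.30), Snai1 (1.98, SE 0.45) and Crebrf (0.72, SE 0.17). Lower were the splicing factor gene Sf3b4 (-0.38, SE 0.08; adjusted p = 0.0182), Chaf1b (-0.48, SE 0.11) and the replication clamp loader gene Chtf18 (-0.49, SE 0.11). For hairpin 2, all 303 DESeq2 genes had an edgeR unadjusted p under 0.05, and 227 kept their sign and that level once the length and GC trend was removed. Higher ones included the long transcripts Myo5a (0.78, SE 0.16; 11702 bases), Hspg2, which encodes perlecan (0.89, SE 0.19; 14187 bases), Med13 (0.57, SE 0.12) and Atf6, an unfolded protein sensor (0.58, SE 0.13). Lower ones included Prmt5, a protein arginine methyltransferase gene (-0.45, SE 0.10), Ung, a DNA repair glycosylase gene (-0.75, SE 0.16), and Pes1 of ribosome assembly (-0.37, SE 0.08). Their median lengths were 7340 bases for higher and 2230 for lower genes. These genes were named after their values were seen, and 21.8% of DESeq2's calls on simulated counts for this comparison were false.

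Across the 9 libraries, the interferon gamma list followed the cytotoxic lymphocyte list (Pearson r = 0.917, permutation p = 7e-05; Spearman rho = 0.983, permutation p = 8e-05). The adjusted permutation p over 3 relations was 0.000105. Without the 2 libraries farthest from the median of the cytotoxic list, r was 0.862 (permutation p = 0.00921). The MHC class I and MHC class II lists gave r = 0.926 and 0.895. The macrophage list went with the interferon gamma list as well (r = 0.866, permutation p = 0.00146), less clearly by rank (Spearman rho = 0.667, permutation p = 0.0587), so the relation may not be particular to lymphocytes. Neither relation gives a direction or a cause.

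Fbxo38 was set against 35 lists that do not contain it. The lowest adjusted permutation p was 0.501, and 1 list had an unadjusted permutation p under 0.05, nuclear oxidative phosphorylation (r = 0.696, permutation p = 0.0361). The 2 libraries farthest from the median Fbxo38 level were replicates 2 and 3 of hairpin 2, the lowest at 11.4 and 11.9 CPM. Every library left stood at 20.9 CPM or more, so values without them do not describe the libraries with the lowest Fbxo38. Without them, r ran from -0.501 to 0.877 over the lists. It was highest for the cGAS STING and T cell lists (0.877 and 0.847; unadjusted permutation p = 0.00485 and 0.00237). No list can be said to follow the Fbxo38 level in these 9 libraries, and a relation, weak or strong, stays open.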
